A study of Homo sapiens with 18 samples.

How the data were processed

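Expression was measured in 3 human cell lines on a 1-colour whole-transcript oligonucleotide array, with 18 arrays in 9 groups of 2. HEK293T is an embryonic kidney line, HaCaT a skin keratinocyte line and HepG2 a liver line. Each line received a scramble siRNA, siRNAs against NF2 and LATS2, or siRNAs against NF2, LATS2, YAP and TAZ. Per the labels' protocols each siRNA oligonucleotide was used at 5 nM, and total RNA was taken 4 days after transfection. The groups with 4 targets thus carried more siRNA in all than those with 2. For scramble only the amount per oligonucleotide was used here, so load may also differ in the contrasts with scramble. Such a difference cannot be told apart from the effect of the targets. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

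The values are the authors' deposited intensities on a linear scale, 1 per probe set, and the submitters' processing notes name RMA, a background correction, normalisation and summary over probes, with no version. The table holds 32321 probe sets. The log2 of each intensity was taken here and nothing else was done to the values. The medians lay between 5.70 and 5.85 on the log2 scale for the HEK293T arrays, between 6.03 and 6.10 for HaCaT and between 6.48 and 6.53 for HepG2. The distributions nearly match within a line and differ between lines, so the lines appear to have been normalised separately, and levels are not compared between lines. Effects within a line are compared between lines. RMA values carry no detection call, and low intensities shrink fold changes. The number of arrays limits the precision.

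Gene names come from the platform annotation, checked by Entrez number against the reference table of genes, where 19128 of 19158 probe sets with 1 gene symbol matched and no symbol needed updating. A further 1388 probe sets list several symbols and 11775 none, and these were named no gene. For each gene the probe set with the highest mean over the arrays was kept, which gave 18404 genes. No coordinates are given, since the array annotation used here names no genome build. Of 330 gene list entries, 306 were measured and the others were not analysed here.

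A linear model of the 9 group means was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 9 residual degrees of freedom and 7.04 prior degrees of freedom. Contrasts were NF2/LATS2 siRNAs minus scramble, all 4 siRNAs minus NF2/LATS2 siRNAs, and all 4 siRNAs minus scramble in each line, the mean of the first over lines, and the differences of the first 2 between lines. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Adjusted p-values in the text are limma's. Errors after ± on a log2 change are standard errors from the model, with n = 2 arrays per group. The 20 gene lists cover YAP/TAZ targets, Hippo components, mitosis, DNA replication, extracellular matrix, actin cytoskeleton, mesenchymal, epithelial junction, hepatocyte, keratinocyte differentiation, basal keratinocyte, HEK293 identity, cholesterol synthesis, interferon response, p53 targets, inflammatory cytokines, EGF ligands, stress response, glycolysis and hypoxia, and RNA interference machinery genes. They were tested with limma's camera at an inter-gene correlation of 0.01, with adjustment over 120 tests, 20 lists by 6 contrasts. Of these, 52 were called, and 18 were also called with an estimated correlation. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The contrasts between lines of the effect of adding YAP and TAZ siRNAs, and the counts over probe sets with no single gene and over small nucleolar RNA genes, were added later.

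The rule names the 4 siRNA targets, the genes with the largest rises and falls per line among called genes whose arrays in 1 group both lie beyond both arrays of the other, the largest among those shared by the lines, the largest differences between lines, the YAP/TAZ target list and the 4 most changed members of each list per contrast, 299 genes in all. The 2 contrasts that share the NF2/LATS2 arrays were set against 50 simulations without effects. The procedure was tested on simulated data for HEK293T NF2/LATS2 siRNAs against scramble over 18404 genes. Of 100 genes changed by 0.5 on the log2 scale 58 were recovered, and of 100 changed by 1, 97 were recovered, with 10 calls among other genes. The simulated noise was independent between genes and alike in all groups, which that of the real arrays was not. The 10 calls are therefore no error rate for the real comparisons. Alternatives were other scalings, variance models, array weights, fits to 1 line, filters, probe set rules, thresholds, a replicate block, each array left out, splits of the shared arrays and other list tests. Cyclic loess scaling and a crossed replicate block were added after the data were seen.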

Results

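Genome-wide expression was measured on 18 arrays from HEK293T, HaCaT and HepG2 cells, 2 arrays for each of 3 siRNA treatments per line. NF2 and LATS2 are parts of the Hippo pathway, which restrains the transcriptional coactivators YAP and TAZ (genes YAP1 and WWTR1). The design asks which genes change when NF2 and LATS2 are targeted, and which of those changes depend on YAP and TAZ. Replicate arrays correlated between 0.991 for HaCaT scramble and 0.999 for HepG2 with all 4 siRNAs. The root mean square SD between replicates was 0.185 on the log2 scale for HaCaT scramble and 0.145 for HepG2 scramble, against 0.0715 for HepG2 with all 4 siRNAs.

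The siRNA targets were examined first. NF2 fell with NF2/LATS2 siRNAs by 1.20 ± 0.12 on the log2 scale in HEK293T, by 0.99 ± 0.12 in HaCaT and by 2.66 ± 0.12 in HepG2 (SE, n = 2 arrays per group; adjusted p = 5.06e-06, 1.77e-05 and 4.15e-09). The LATS2 transcript fell by 0.59 ± 0.08 in HepG2 (adjusted p = 0.000151), but its change was -0.12 ± 0.08 in HEK293T (adjusted p = 0.316) and 0.05 ± 0.08 in HaCaT (adjusted p = 0.823), both arrays lying below both scramble arrays in HEK293T. With all 4 siRNAs LATS2 was lower than in scramble arrays by 0.58 in HEK293T, 0.69 in HaCaT and 1.32 in HepG2. The arrays are therefore described here as labelled NF2/LATS2. In HEK293T and HaCaT only NF2 passed the test as lower in them, which does not show that the LATS2 siRNA was without effect. When YAP and TAZ siRNAs were added, YAP1 fell by 1.39, 1.32 and 2.62 and WWTR1 fell by 1.69, 2.00 and 1.32 in HEK293T, HaCaT and HepG2, all with adjusted p of 5.32e-07 or less. WWTR1 was higher by 0.36 in HaCaT NF2/LATS2-labelled arrays (adjusted p = 0.00769).

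**Figure D1:**
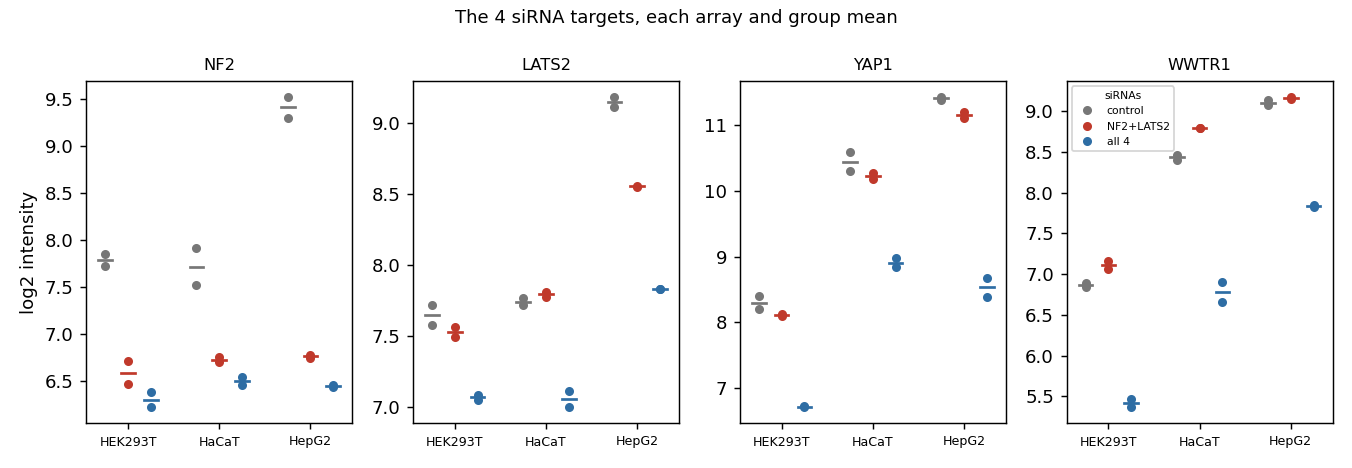
Log2 intensity of the siRNA targets on each array (points, 2 per group) with the group mean (line), by cell line and siRNAs. NF2 is lower in both arrays of each group that received its siRNA, and LATS2 in the NF2/LATS2-labelled arrays changed by -0.12 in HEK293T and 0.05 in HaCaT, neither passing the test.

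In HEK293T, the 3 largest rises in NF2/LATS2-labelled arrays were of known YAP/TAZ target genes. CCN2, a matricellular growth factor gene, rose 16.7-fold (log2 4.06 ± 0.09, adjusted p = 2.6e-14), CCN1 rose 5.51-fold (2.46 ± 0.10) and ANKRD1, encoding an ankyrin repeat protein, rose by 2.39 ± 0.12 on the log2 scale. TUFT1, PLK2, GADD45B and RND3 rose by 1.63, 1.52, 1.48 and 1.45. Of 14 inflammatory cytokine genes 3 rose and 0 fell, over all genes and adjusted over the list alone, among them the NF-kappaB inhibitor genes NFKBIA by 1.13 and TNFAIP3 by 0.94 (adjusted p = 0.00217; adjusted p = 0.0504 with an estimated correlation). The largest falls were PCK1, the rate-limiting enzyme of gluconeogenesis, by 2.26 ± 0.10, SLITRK3 by 1.72, SMIM19 by 1.69, BRCA1 by 1.67, UEVLD by 1.61 and CA2, a carbonic anhydrase, by 1.60. Of the 8 measured HEK293 identity genes 4 fell and 0 rose, also when adjusted over the list alone, among them EYA1 by 0.88 and NEFM by 0.66 (camera adjusted p = 0.00657; adjusted p = 0.0642 with an estimated correlation). Of 21 matrix genes 9 rose and 1 fell, also when adjusted over the list alone, with THBS1 up by 1.02 and COL12A1 by 0.78 (adjusted p = 0.000693; adjusted p = 0.071 with an estimated correlation). In all, 1396 genes were higher and 2398 lower, 45 and 138 of them at least 2-fold. The higher share, 36.8%, was 24.9% with quantile normalisation over all arrays, 24% within the line and 16.3% with median centring.

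Signal in probe sets with no single gene set the HEK293T NF2/LATS2-labelled arrays apart, while other measures were shared in part with HepG2, and those over such probe sets and small nucleolar RNA genes were chosen after values were seen. Of 13163 probe sets with no single gene, 1848 were higher and 375 lower in them, against 93 higher in HaCaT and 12 in HepG2. Of 175 small nucleolar RNA genes 71 were higher and 1 lower in HEK293T (median log2 change 0.28), and 0 higher and 41 lower in HepG2 (median log2 change -0.23). Of the 2398 genes called lower in HEK293T, 88.0% were also lower in replicate 1 than in replicate 2 in the mean of the other HEK293T groups, against 53.8% of genes not called, with a median gap of -0.11 beside a median fall of -0.48. Over all genes that replicate gap correlated with the change after NF2/LATS2 siRNAs at 0.397 in HEK293T, 0.368 in HepG2 and -0.101 in HaCaT. In HaCaT the deviations of same-numbered arrays in the averaged groups correlated at -0.46, so their mean can cancel a shared part. The value of -0.101 therefore cannot show whether HaCaT shares this pattern. In HepG2 59.2% of the genes called lower and 23.1% of those called higher were lower in replicate 1. Leaving out 1 array took the number of changed genes from 3794 to 1916 in HEK293T, without scramble replicate 2, and from 1112 to 386 in HepG2, without NF2/LATS2 replicate 2.

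In HaCaT, NF2/LATS2-labelled arrays showed higher inflammatory and sterol synthesis genes and lower basal keratinocyte genes. MFAP5, a microfibril component, rose 39.3-fold (5.29 ± 0.13, adjusted p = 2.39e-13). The adhesion molecule gene ICAM1 rose by 3.33 ± 0.12, the cytokine genes IL1A, CXCL8 and IL1B by 3.02, 2.95 and 2.71, and TNF, which is not on the cytokine list, by 3.18. Of 14 inflammatory cytokine genes 10 rose and none fell (median 0.92, adjusted p = 4.99e-13), also when adjusted over the list alone. Of 11 cholesterol synthesis genes 10 rose (median 1.75, adjusted p = 4.44e-22), also when adjusted over the list alone, with INSIG1 up by 3.10, HMGCS1 by 2.80 and DHCR7 by 2.27. S100A8, a calcium-binding protein of stressed epidermis, fell 14.6-fold (log2 -3.87 ± 0.12), CLCA2 fell by 2.95 and KRT13 by 2.92. Of 8 basal keratinocyte genes 6 fell, including KRT15 by 2.86, ITGA6 by 1.03 and KRT5 by 0.67 (adjusted p = 3.04e-07), and matrix genes rose in 12 of 21 cases and fell in 2 (adjusted p = 1.09e-05), both with the same numbers adjusted over the list alone. The keratinocyte differentiation list, which holds KRT13, was not called, with 4 of 20 genes higher and 6 lower, also when adjusted over the list alone (median -0.05, adjusted p = 0.297). The cytokine, cholesterol, basal keratinocyte and matrix calls held with an estimated correlation. In all, 1602 genes were higher and 1344 lower, 181 and 113 at least 2-fold. The higher share, 54.4%, was 67.4% without scramble replicate 1 and 43.4% without scramble replicate 2, so 1 array turned the balance. Without NF2/LATS2 replicate 1 or 2 the number changed was 1752 or 1829 instead of 2946, with the remaining array assumed to vary like the other groups, and it was 1875 with array weights and 1622 with only the 6 HaCaT arrays.

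In HepG2, fewer genes were called in NF2/LATS2-labelled arrays. The long non-coding RNA UCA1 rose 5.07-fold (2.34 ± 0.26, adjusted p = 3.09e-05), the amino acid transporter gene SLC7A7 by 2.22, the natriuretic peptide gene NPPB by 2.12, the membrane repair gene MYOF by 1.93, the chaperone gene CRYAB by 1.88 and ANXA1 by 1.75. After NF2 itself, the largest falls were TSPAN8 by 1.73 and UEVLD by 1.69, and ACSM3 fell by 1.19 and PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, by 1.12. Of 18 hepatocyte genes 1 fell and 0 rose, and 3 fell and 0 rose adjusted over the list alone, with no call for the list (adjusted p = 0.405). The gene called over all genes was APOA1, at -0.38 (adjusted p = 0.0241), and its change was 0.063 (adjusted p = 0.862) with its probe sets averaged. In all, 676 genes were higher and 436 lower, 47 and 15 at least 2-fold. This count depended on single arrays, with 1970 genes without scramble replicate 1, 461 without scramble replicate 2, 494 without NF2/LATS2 replicate 1 and 386 without NF2/LATS2 replicate 2, against 1112.

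The YAP/TAZ target list, fixed from earlier knowledge of the pathway, rose in each line. In HEK293T 11 of 21 members were higher and 1 lower (median 0.37, adjusted p = 1.83e-07), in HaCaT 14 higher and 0 lower (median 0.84, adjusted p = 3.96e-19) and in HepG2 10 higher and 0 lower (median 0.30, adjusted p = 2.7e-12). Adjusted over the list alone, 11 were higher and 2 lower, 15 and 0, and 11 and 0. When YAP and TAZ siRNAs were added the list fell in each line, with 10 members lower and 3 higher in HEK293T (median -0.25), 19 lower and 0 higher in HaCaT (median -1.40) and 12 lower and 2 higher in HepG2 (median -0.52). Adjusted over the list alone these were 11 and 3, 19 and 0, and 12 and 2. These 6 calls held with an estimated correlation, with adjusted p between 0.00733 and 0.031.

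**Figure D2:**
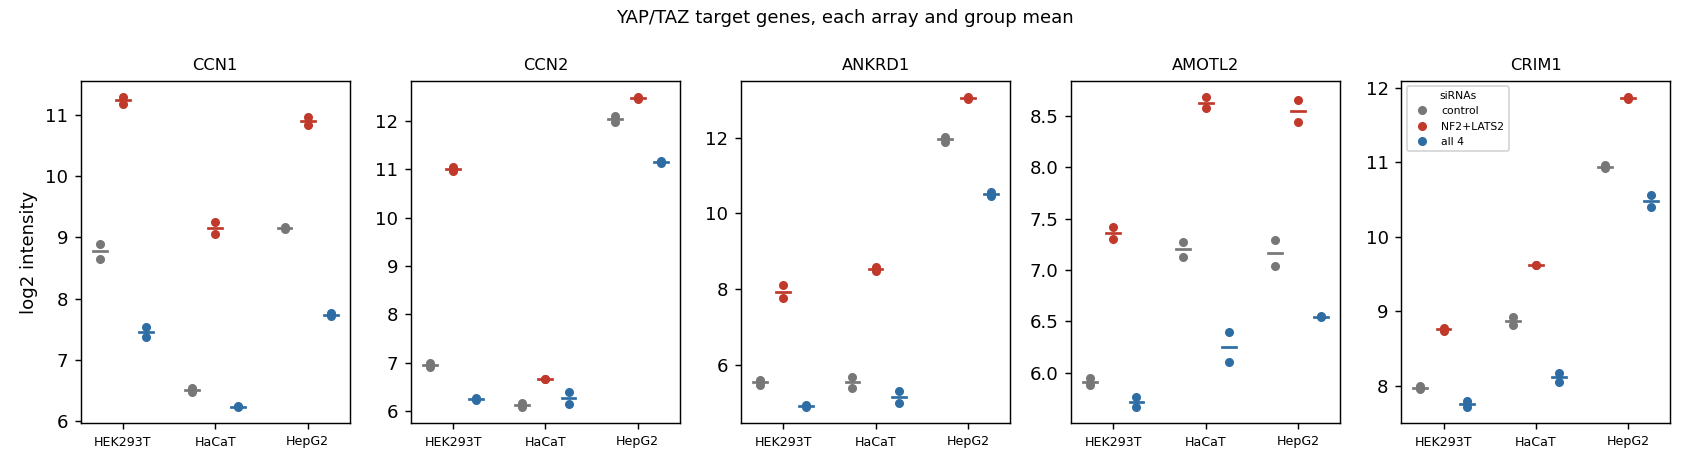
Log2 intensity of 5 YAP/TAZ target genes on each array (points, 2 per group) with the group mean (line), by cell line and siRNAs. CCN1, ANKRD1, AMOTL2 and CRIM1 rise with NF2/LATS2 siRNAs and fall when YAP and TAZ siRNAs are added in each line, while the rise of CCN2 is 4.06 on the log2 scale in HEK293T and 0.54 and 0.43 in HaCaT and HepG2.

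Genes that moved 1 way in NF2/LATS2-labelled arrays and the other way with YAP and TAZ siRNAs were counted next. Of the genes higher in HEK293T, 681 of 1396 fell again, in HaCaT 1006 of 1602 and in HepG2 271 of 676, against 90.3, 261 and 80.8 for independent lists. Of the genes lower, 1612 of 2398 rose again in HEK293T, 738 of 1344 in HaCaT and 181 of 436 in HepG2, against 310, 205 and 53.5. In HaCaT, MFAP5, INSIG1 and TNF fell back by 5.64, 3.39 and 3.04, whereas IL1B did not (0.03, adjusted p = 0.848) and stayed 2.74 above scramble. In HepG2, SLC7A7, NPPB and CRYAB fell back by 2.51, 2.52 and 1.90, and the fall of PPARGC1A was not reversed (-0.10, adjusted p = 0.584). Against scramble, 11.8% of the genes higher in HEK293T were still higher with all 4 siRNAs, 35.3% in HaCaT and 55.0% in HepG2. The contrast of all 4 siRNAs with scramble shares the scramble arrays with the first. It called 428, 2724 and 2758 of all 18404 genes higher in HEK293T, HaCaT and HepG2, so these shares do not rank the lines. The median change of these genes against scramble was 0.12, 0.07 and 0.33. The 2 contrasts correlated across genes at 0.30, 0.11 and 0.29, against 0.50 simulated without effects, with covariances of 0.0154, 0.0172 and 0.0236 against simulated ones of 0.00617, 0.00614 and 0.00619. The contrast of NF2/LATS2 siRNAs and that of added YAP and TAZ siRNAs share the NF2/LATS2-labelled arrays. Simulations without effects gave 0 genes that moved 1 way and then the other. Without effects few genes pass the threshold in either contrast, so this 0 is no reference for the observed counts. The simulated noise was also independent between genes. The simulated correlation across genes was -0.50, against -0.81 observed in HEK293T, -0.46 in HaCaT and -0.24 in HepG2, genes not being independent replicates. The covariances were -0.0681, -0.0796 and -0.0190, and their differences from the simulated ones were -0.0619, -0.0734 and -0.0128. Part of the excess over independent lists may come from the spread estimate that both contrasts use, and part from the shared arrays. In HEK293T these are the arrays in which 1848 probe sets with no single gene were higher. A split of the shared arrays leaves 1 array on each side. Where the shared arrays were split between the contrasts the numbers of rises that fell again were 201 or 190 in HEK293T, 557 or 535 in HaCaT and 102 or 101 in HepG2. With each array centred on its median the rises that fell again in HEK293T numbered 324, and with only the 6 HaCaT arrays those in HaCaT numbered 627 and the falls that rose again 384. With 1 array left out, the rises that fell again numbered 388 without HEK293T scramble replicate 2, 434 without either NF2/LATS2 replicate and 376 without 4-siRNA replicate 2, and the falls that rose again 1008, 1056 and 934 without scramble replicate 2, NF2/LATS2 replicate 2 and 4-siRNA replicate 2. In HaCaT the rises numbered 661 without NF2/LATS2 replicate 1, and the falls 489 without scramble replicate 1 and 445 and 434 without NF2/LATS2 replicates 1 and 2. In HepG2 the rises numbered 161, 140 and 142 and the falls 107, 94 and 76 without scramble replicate 2 and NF2/LATS2 replicates 1 and 2.

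Genes shared by the lines were few and led by YAP/TAZ targets. In NF2/LATS2-labelled arrays 49 genes were higher in all 3 lines, against 4.46 for independent lists, and 19 of them were also lower with YAP and TAZ siRNAs in all 3. By mean change over the lines the largest of these 19 were CCN1 (2.46, 2.64 and 1.74 in HEK293T, HaCaT and HepG2), ANKRD1 (2.39, 2.99 and 1.10), CCN2 (4.06, 0.54 and 0.43), NUAK2 (1.27, 2.08 and 1.16), AMOTL2 (1.45, 1.43 and 1.38), THBS1 (1.02, 1.97 and 0.75), NPPB (0.98, 0.43 and 2.12), HSPB8 (0.44, 0.84 and 1.45) and CRIM1 (0.78, 0.75 and 0.93). DHCR7, TIMP2 and GPCPD1 were higher in all 3 without falling in all 3. A further 19 genes were lower in all 3 lines, against 4.15 for independent lists, including NF2, UEVLD, RTKN, NDRG1, RAP1A and BAZ2B. The lines share 1 estimate of the spread per gene, so calls in them are not independent even without a shared effect. The references of 4.46 and 4.15 leave this out. Of single arrays, HEK293T scramble replicate 1, HEK293T NF2/LATS2 replicates 1 and 2, HepG2 scramble replicate 2 and HepG2 NF2/LATS2 replicates 1 and 2 each lowered the 49 rises when left out, to 27, 26, 31, 28, 25 and 24 in that order. The 19 falls became 51 without HaCaT scramble replicate 2, 10 without HaCaT NF2/LATS2 replicate 2, 10 without HepG2 scramble replicate 2 and 8 without either HepG2 NF2/LATS2 replicate, and the 19 rises that fell in all 3 became 11 without HEK293T NF2/LATS2 replicate 2 and 10 without HepG2 NF2/LATS2 replicate 1. With each array centred on its median the 49 rises became 22 and the 19 that fell in all 3 became 12. The 19 falls became 33 and 50 with quantile normalisation over all arrays and within each line, 39 with cyclic loess, a scaling chosen after the data were seen, 30 with a trended, robust variance and 11 with only the 6 arrays of each line. Averaged over the lines, 1736 genes were higher and 2018 lower. Across all genes the changes in NF2/LATS2-labelled arrays correlated weakly between lines, with r of 0.11 for HEK293T and HaCaT, 0.04 for HEK293T and HepG2 and 0.16 for HaCaT and HepG2, genes not being independent replicates.

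Adding YAP and TAZ siRNAs moved cell cycle genes in HaCaT and HepG2. In HaCaT all 18 mitosis genes and all 18 DNA replication genes fell, also when adjusted over the list alone, with medians of -3.49 and -1.76 (adjusted p = 3.72e-29 and 4.44e-22). MKI67, a proliferation marker, fell by 4.29, the mitotic kinase gene CDK1 by 4.23, CDC6 by 3.35 and RRM2 by 3.31. In HepG2 all members of both lists fell, also when adjusted over the list alone, with medians of -1.61 and -1.14 (adjusted p = 7.06e-28 and 2.76e-21), including TTK by 2.08, CENPF by 2.02 and CDC45 by 1.70. In HEK293T 7 mitosis genes rose and 0 fell, also when adjusted over the list alone (median 0.17, adjusted p = 0.00774; adjusted p = 0.564 with an estimated correlation), MKI67 by 0.74 and CENPF by 0.57. In the NF2/LATS2-labelled HEK293T arrays the mitosis list had been lower than in scramble (median -0.17, 5 of 18 genes lower), so its rise went towards the scramble level. The HaCaT and HepG2 calls held with an estimated correlation. Tested as a difference between lines, the mitosis list had a median of 3.75 for HEK293T minus HaCaT and 1.80 for HEK293T minus HepG2 (adjusted p = 7.29e-27 and 1.35e-24; adjusted p = 0.0217 and 0.025 with an estimated correlation).

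**Figure D3:**
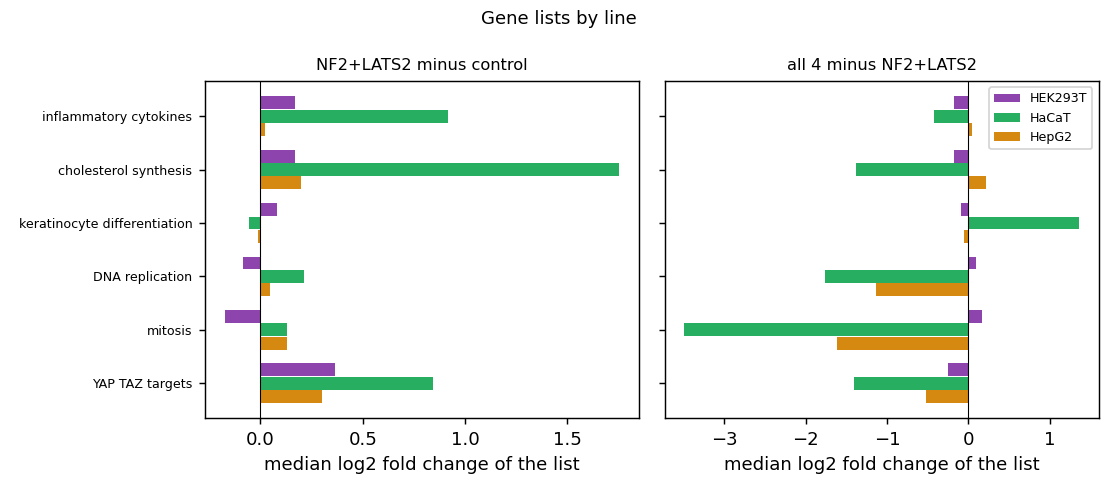
Median log2 fold change of 6 gene lists by line, for NF2/LATS2 siRNAs minus scramble (left) and for all 4 siRNAs minus NF2/LATS2 siRNAs (right). On the right the mitosis list reaches -3.49 in HaCaT and -1.61 in HepG2 and 0.17 in HEK293T.

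HaCaT cells with YAP and TAZ siRNAs added also showed higher epidermal differentiation genes, 16 of 20 rising and 1 falling, also when adjusted over the list alone (median 1.36, adjusted p = 3.53e-13, held with an estimated correlation). CNFN rose by 5.20, the suprabasal keratin gene KRT10 by 4.53 and the cornified envelope genes SPRR1B and SPRR1A, close paralogs whose probes can share signal, by 4.49 and 4.39. S100A8 rose 64.8-fold and KRT23 by 5.24. Basal keratinocyte genes rose too, 4 of 8 higher and 0 lower (median 0.41, camera adjusted p = 0.00779, and 0.297 with an estimated correlation). The median log2 intensity of that list was 11.78 with all 4 siRNAs, 10.22 with NF2/LATS2 siRNAs and 11.39 with scramble. Cholesterol synthesis genes fell in 10 of 11 cases (median -1.39) and cytokine genes fell in 8 of 14 and rose in 2, both with the same numbers adjusted over the list alone and both held with an estimated correlation (adjusted p = 0.031 for each), among them CCL2, which fell by 4.38, ICAM1, which fell by 2.93, and IL6, which fell by 2.08. CCL5, a chemokine gene not on that list, fell by 5.68. The cell cycle inhibitor gene CDKN1A rose by 2.18. In all, 2805 genes were higher and 3001 lower, 355 and 682 at least 2-fold. The higher share, 48.3%, was 53.1% with quantile normalisation over all arrays and 51.9% within the line, so the balance of all calls turned with the scaling.

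HepG2 cells with YAP and TAZ siRNAs added showed higher liver genes, 7 of 18 hepatocyte genes rising and 0 falling, and 8 and 0 adjusted over the list alone (median 0.19, adjusted p = 0.000106; adjusted p = 0.102 with an estimated correlation). FGB, FGG and FGA, encoding fibrinogen chains, rose by 1.11, 0.68 and 0.63, and the glucuronosyltransferase gene UGT2B4 by 4.25, the water channel gene AQP3 by 3.29 and VNN1 by 3.05. Actin cytoskeleton genes fell in 12 of 19 cases and rose in 1, and 14 and 2 adjusted over the list alone, TAGLN by 1.73 and ANLN by 2.19 (adjusted p = 9.48e-06; adjusted p = 0.0837 with an estimated correlation). In all, 2258 genes were higher and 2199 lower, 257 and 351 at least 2-fold, and 6955 instead of 4457 were called with array weights. In HEK293T 2375 genes were higher and 1191 lower, led by OSTN, up by 2.79, and by CCN2 and CCN1, down by 4.76 and 3.78, and 2316 genes were called without NF2/LATS2 replicate 2 and 1744 without 4-siRNA replicate 2, against 3566. With all 4 siRNAs against scramble, 780 genes changed in HEK293T, 5477 in HaCaT and 5198 in HepG2, and the HEK293T count was 331 and 413 without scramble replicates 1 and 2, 284 and 323 without 4-siRNA replicates 1 and 2, 1208 without either HaCaT scramble replicate and 493 with only the 6 HEK293T arrays, and the HaCaT count was 3535 with array weights.

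The effects of NF2/LATS2 siRNAs were compared between lines by testing their difference, on lines that appear to have been normalised separately and arrays whose LATS2 transcript passed the test as lower in HepG2 and not in HEK293T or HaCaT. The rise of CCN2 was larger in HEK293T than in HaCaT by 3.52 ± 0.12 and than in HepG2 by 3.63 ± 0.12 (adjusted p = 3.08e-11 and 3.77e-11). In HaCaT scramble arrays CCN2 lay at 6.16 and 6.08 on the log2 scale, near the array medians of 6.03 and 6.09. In HepG2 scramble arrays it lay at 12.11 and 11.99, far above the medians of 6.51 and 6.50. Whether these starting levels limited the rises was not tested. The rises of MFAP5, INSIG1 and ICAM1 were larger in HaCaT than in HepG2 by 5.41, 3.12 and 3.20. CRYAB rose by 1.88 in HepG2 and fell by 0.80 in HEK293T, with a difference of HEK293T minus HepG2 of -2.67. CCN1 did not differ detectably between HEK293T and HaCaT (-0.18 ± 0.14, adjusted p = 0.45). The effect differed in 3461 genes between HEK293T and HaCaT, in 2773 between HEK293T and HepG2 and in 1933 between HaCaT and HepG2. Without HEK293T scramble replicate 2 and HepG2 NF2/LATS2 replicates 1 and 2 the count for HEK293T and HepG2 was 1590, 1759 and 1672, and without HepG2 NF2/LATS2 replicates 1 and 2 that for HaCaT and HepG2 was 1266 and 1287.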

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

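Of the tests below, those of probe sets with no single gene, of knockdown strength, of siRNA load, of cyclic loess scaling and of the effect of added YAP and TAZ siRNAs between lines were chosen only after results had been seen, and for the replicates of the other HEK293T groups and for UEVLD related values were already known. The first results to look at again are differences between lines, each found by a test of the difference. The effect of NF2/LATS2 siRNAs differed in 3461 genes between HEK293T and HaCaT, 2773 between HEK293T and HepG2 and 1933 between HaCaT and HepG2, and the effect of adding YAP and TAZ siRNAs differed in 5835, 4513 and 3967 genes. For NF2/LATS2 siRNAs, the cholesterol synthesis list had a median difference of -1.37 for HEK293T minus HaCaT and 1.57 for HaCaT minus HepG2, and the cytokine list -0.59 and 0.80. For added YAP and TAZ siRNAs, HEK293T minus HaCaT was 3.75 for mitosis, 1.77 for DNA replication and -1.44 for keratinocyte differentiation. HEK293T minus HepG2 was 1.80 for mitosis and 1.30 for DNA replication. HaCaT minus HepG2 was 1.43 for keratinocyte differentiation, -1.61 for cholesterol synthesis, 0.56 for p53 targets and -0.50 for cytokines. Signal also changed in probe sets that name no single gene and enter no comparison of genes, in 2223 of them for NF2/LATS2 siRNAs in HEK293T, 179 in HaCaT and 35 in HepG2, and in 1829, 675 and 348 when YAP and TAZ siRNAs were added.

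The 2398 falls in HEK293T were weighed first. Scalings could not decide on a difference in intensity distribution or an intensity-dependent trend as the cause. With quantile normalisation within each line 3417 genes were called lower, all 2398 among them. With cyclic loess 2810 were called lower, 2385 of the 2398 among them. Both scalings were fitted over all probe sets, including those with no single gene. They moved the median change over all genes from 0.023 to -0.059 and -0.028, and such a shift by itself adds falls. Variation that also parts the replicates of the other HEK293T groups remains open, as 88.0% of the falls were lower in replicate 1 of those groups, although the median gap there was -0.11 against a fall of -0.48, so the labelled arrays would have to lie further along it. A property of both RNA preparations, for example unspliced RNA or genomic DNA, also remains open, as 1848 probe sets with no single gene rose in HEK293T against 93 in HaCaT. Any of these could produce falls that return when the 4-siRNA arrays are compared with the same arrays. The 1612 such genes may therefore be partly technical, and a biological response to NF2 loss stays untested for them.

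The fall of mitosis and DNA replication genes in HaCaT and not in HEK293T was weighed next. Weaker knockdown of both genes in HEK293T is argued against by YAP1, whose change there differed from that in HaCaT by -0.069 ± 0.15, but WWTR1 fell less in HEK293T, by a difference of 0.32 ± 0.12, so a contribution of weaker WWTR1 knockdown stays open, although WWTR1 fell still less in HepG2 (-1.32 against -1.69), where all 36 mitosis and DNA replication genes were lower and YAP1 fell further (-2.62). An effect of siRNA load alike in every line is argued against by a HEK293T median of 0.14 over the 36 genes, none of them lower. That median is against NF2/LATS2-labelled arrays, in which the mitosis list was already lower than in scramble (median -0.17), which limits the argument. A load effect particular to a line remains open, since load and YAP/TAZ targeting were never separated, and a dependence of proliferation on YAP and TAZ that differs between the lines is a hypothesis these arrays leave standing.

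The genes lower in all 3 lines were weighed last, without NF2. Of the 18, 11 were higher with YAP and TAZ siRNAs in 2 or more lines, which lies between the bounds set for dependence on YAP and TAZ. Such dependence cannot be told apart from other origins for the set. The 18 were also picked as low in the arrays that this contrast subtracts, so part of the return is built in. Off-target silencing by the NF2 or LATS2 siRNAs is argued against as the origin of the whole set, as 3 of the 18 stayed called lower than scramble in all 3 lines with all 4 siRNAs present, a test limited by the 780 genes called in HEK293T. It may still apply to those 3, UEVLD, RAP1A and INTS1, and to RTKN (-0.51, -0.28 and -0.76 against scramble in HEK293T, HaCaT and HepG2), SNX7 (-0.41, -0.16 and -1.01) and POLR1D (-0.25, -0.44 and -0.58), each called lower in 2 lines, with INTS1 and POLR1D named after their values were seen and siRNA sequences not used here.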

How the results depend on the processing

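Of the alternatives below, tests with cyclic loess scaling and with crossed replicate numbers were chosen only after the data were seen. Genes are counted here for the NF2/LATS2 effect, the YAP/TAZ effect of the added siRNAs, the 4-target effect against scramble, and their overlaps and differences. Across 34 alternatives, 575 of 693 counts stayed within a fixed ratio of the reported value, 109 were lower and 9 higher. Leaving out 1 array moves the counts of the other lines only through the pooled spread. Part of this stability was therefore fixed in advance. List tests kept their side of the threshold in 3595 of 3720 cases and named genes in 23997 of 25322. Stricter thresholds can only lower these counts of calls, and for the other shifts the cause was not tested. Tests of every probe set were not run for the lists or named genes, nor the 2-fold threshold for the lists. The YAP/TAZ target list kept its call in all 6 contrasts under every alternative run. With quantile normalisation over all 18 arrays the number was 33 for the falls in all 3 lines. With each array centred on its median the numbers were 324 for the rises that fell again in HEK293T, 22 for the rises in all 3 lines and 12 for the rises that fell again in all 3 lines. With quantile normalisation within each line the number was 50 for the falls in all 3 lines. With cyclic loess within each line the number was 39 for the falls in all 3 lines. With a trended, robust variance the number was 30 for the falls in all 3 lines. With array weights the numbers were 1875 for the NF2/LATS2 effect in HaCaT, 3535 for the 4-target effect in HaCaT and 6955 for the YAP/TAZ effect in HepG2. With only the 6 arrays of each line the numbers were 493 for the 4-target effect in HEK293T, 1622 for the NF2/LATS2 effect in HaCaT, 627 for the rises that fell again in HaCaT, 384 for the falls that rose again in HaCaT and 11 for the falls in all 3 lines. At an adjusted p under 0.01 the numbers were 2243 for the NF2/LATS2 effect in HEK293T, 2110 for the YAP/TAZ effect in HEK293T, 263 for the 4-target effect in HEK293T, 312 for the rises that fell again in HEK293T, 987 for the falls that rose again in HEK293T, 1823 for the NF2/LATS2 effect in HaCaT, 440 for the falls that rose again in HaCaT, 527 for the NF2/LATS2 effect in HepG2, 149 for the rises that fell again in HepG2, 100 for the falls that rose again in HepG2, 16 for the rises in all 3 lines, 7 for the falls in all 3 lines, 10 for the rises that fell again in all 3 lines, 2203 for the mean effect, 2004 for the difference HEK293T minus HaCaT, 1332 for the difference HEK293T minus HepG2 and 1075 for the difference HaCaT minus HepG2. At an adjusted p under 0.05 and at least 2-fold the numbers were 183 for the NF2/LATS2 effect in HEK293T, 190 for the YAP/TAZ effect in HEK293T, 20 for the 4-target effect in HEK293T, 29 for the rises that fell again in HEK293T, 75 for the falls that rose again in HEK293T, 294 for the NF2/LATS2 effect in HaCaT, 1037 for the YAP/TAZ effect in HaCaT, 785 for the 4-target effect in HaCaT, 119 for the rises that fell again in HaCaT, 62 for the falls that rose again in HaCaT, 62 for the NF2/LATS2 effect in HepG2, 608 for the YAP/TAZ effect in HepG2, 615 for the 4-target effect in HepG2, 25 for the rises that fell again in HepG2, 6 for the falls that rose again in HepG2, 4 for the rises in all 3 lines, 1 for the falls in all 3 lines, 4 for the rises that fell again in all 3 lines, 33 for the mean effect, 508 for the difference HEK293T minus HaCaT, 307 for the difference HEK293T minus HepG2 and 333 for the difference HaCaT minus HepG2. With NF2/LATS2 replicate 1 in the first contrast and 2 in the second the numbers were 201 for the rises that fell again in HEK293T, 682 for the falls that rose again in HEK293T, 557 for the rises that fell again in HaCaT, 338 for the falls that rose again in HaCaT, 102 for the rises that fell again in HepG2, 45 for the falls that rose again in HepG2 and 6 for the rises that fell again in all 3 lines. With NF2/LATS2 replicate 2 in the first contrast and 1 in the second the numbers were 190 for the rises that fell again in HEK293T, 699 for the falls that rose again in HEK293T, 535 for the rises that fell again in HaCaT, 332 for the falls that rose again in HaCaT, 101 for the rises that fell again in HepG2, 67 for the falls that rose again in HepG2 and 7 for the rises that fell again in all 3 lines.

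HEK293T NF2/LATS2 calls were 36.8% higher, against 24.9% with quantile normalisation over all arrays, 24% within the line and 16.3% with median centring. Its YAP/TAZ calls were 66.6% higher, against 77.2% within the line and 80.4% with median centring, and its 4-target calls 54.9% against 47.9% with quantile normalisation over all arrays, 49.9% within the line and 43.3% with median centring. Single arrays moved that 4-target share either way, to 42.3% and 71.2% without scramble replicates 1 and 2 and to 68.3% and 43.3% without 4-siRNA replicates 1 and 2. HaCaT YAP/TAZ calls were 48.3% higher, against 53.1% with quantile normalisation over all arrays, 51.9% within the line, 41.6% with median centring and 34.2% at 2-fold. Its 4-target calls were 49.7% higher, against 55.5% over all arrays, 54.1% within the line, 45.3% with median centring and 36.3% at 2-fold. HepG2 YAP/TAZ calls were 50.7% higher against 42.3% at 2-fold, and its 4-target calls 53.1% against 48.8%. APOA1 in HepG2 changed sign, from -0.38 to 0.063 (adjusted p = 0.862), when its probe sets were averaged.

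Over 9 pairs of groups the deviations of same-numbered arrays correlated between -0.46, for HaCaT scramble and 4-siRNA arrays, and 0.34. The 2 pairs over 0.1 were both in HEK293T. There r was 0.335 for scramble and 4-siRNA arrays and 0.102 for NF2/LATS2 and 4-siRNA arrays. For HEK293T scramble and NF2/LATS2 arrays it was 0.0997, so the replicate number may carry a shared part in this line. With the replicate number as a block the NF2/LATS2 effect was 3556 genes in HEK293T, 2745 in HaCaT and 976 in HepG2, and no count or target list call moved past its bound. With the HaCaT scramble numbers crossed the 4-target effect in HaCaT was 5974 genes against 5299 with the numbers as labelled.

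Without each array in turn, the lone array of a group being assumed to vary like the others, the lowest and highest values were 1916 and 4479 for the NF2/LATS2 effect in HEK293T, 1744 and 4237 for the YAP/TAZ effect in HEK293T, 284 and 1208 for the 4-target effect in HEK293T, 376 and 896 for the rises that fell again in HEK293T, 934 and 1873 for the falls that rose again in HEK293T, 1752 and 3622 for the NF2/LATS2 effect in HaCaT, 4368 and 6321 for the YAP/TAZ effect in HaCaT, 3956 and 6424 for the 4-target effect in HaCaT, 661 and 1103 for the rises that fell again in HaCaT, 434 and 968 for the falls that rose again in HaCaT, 386 and 1970 for the NF2/LATS2 effect in HepG2, 3131 and 4944 for the YAP/TAZ effect in HepG2, 3750 and 5686 for the 4-target effect in HepG2, 140 and 339 for the rises that fell again in HepG2, 76 and 239 for the falls that rose again in HepG2, 24 and 67 for the rises in all 3 lines, 8 and 51 for the falls in all 3 lines, 10 and 23 for the rises that fell again in all 3 lines, 2813 and 4585 for the mean effect, 2345 and 3898 for the difference HEK293T minus HaCaT, 1590 and 3466 for the difference HEK293T minus HepG2, 1266 and 2842 for the difference HaCaT minus HepG2, 0.33 and 0.37 for the target list in HEK293T after NF2/LATS2 siRNAs, 0.72 and 0.90 for the target list in HaCaT after NF2/LATS2 siRNAs, 0.21 and 0.40 for the target list in HepG2 after NF2/LATS2 siRNAs, -0.39 and -0.25 for the target list in HEK293T with YAP and TAZ siRNAs, -1.43 and -1.38 for the target list in HaCaT with YAP and TAZ siRNAs, -0.57 and -0.46 for the target list in HepG2 with YAP and TAZ siRNAs. Most of the highest counts came without a HaCaT scramble array, the group with the widest spread between replicates. Low intensities compress folds, and no measure of signal over background was used here.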

Other observations

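Of the tests below, only the counts over small nucleolar RNA genes were chosen after the result was seen. Most other gene lists that were called lost the call with an estimated correlation. In HaCaT with NF2/LATS2 siRNAs, 7 of 14 stress response genes rose and 1 fell, and 9 and 1 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). There 8 of 19 actin genes rose, and 10 adjusted over the list alone (adjusted p = 0.095 with an estimated correlation), 8 of 24 Hippo component genes rose, and 9 adjusted over the list alone (adjusted p = 0.494 with an estimated correlation), and 2 of 6 EGF ligand genes rose, and 3 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation). The hepatocyte list, with a median log2 intensity of 5.50 in the scramble arrays of this line, had 7 of 18 genes lower, also when adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). Of 18 DNA replication genes 6 rose there, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.494 with an estimated correlation). In HEK293T arrays labelled NF2/LATS2, 5 of 18 mitosis genes fell, also when adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). In HepG2 with NF2/LATS2 siRNAs, 4 of 11 cholesterol synthesis genes rose, also when adjusted over the list alone (adjusted p = 0.214 with an estimated correlation), and 3 of 18 mitosis genes rose, and 5 adjusted over the list alone (adjusted p = 0.532 with an estimated correlation).

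In HepG2 with YAP and TAZ siRNAs added, 7 of 14 epithelial junction genes rose, RAB25 by 1.18 and ELF3 and SPINT1 each by 0.84, and 9 rose and 1 fell adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). Of 15 glycolysis and hypoxia genes 6 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.564 with an estimated correlation). Of 17 interferon response genes 4 rose, also when adjusted over the list alone (adjusted p = 0.457 with an estimated correlation). Of 24 Hippo component genes 12 fell and 1 rose, and 12 and 3 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). In HaCaT with these siRNAs added, 7 of 13 p53 target genes rose and 1 fell, TP53INP1 rising by 2.30, and 8 and 1 adjusted over the list alone (adjusted p = 0.0719 with an estimated correlation). The mesenchymal and RNA interference machinery lists were called by camera in none of the 6 contrasts, with lowest adjusted p of 0.677 and 0.314. The fry test of limma called the mesenchymal list in HaCaT with NF2/LATS2 siRNAs (adjusted p = 0.0248) and with YAP and TAZ siRNAs added in HaCaT (adjusted p = 0.01) and HepG2 (adjusted p = 0.0448), its members being called in both directions in each.

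BRCA1, a DNA repair gene, fell by 1.67 in HEK293T arrays labelled NF2/LATS2 and rose by 1.93 when YAP and TAZ siRNAs were added, while in HaCaT and HepG2 it fell by 2.72 and fell by 1.84 with those siRNAs. Of 175 small nucleolar RNA genes 71 were higher and 1 lower in HEK293T arrays labelled NF2/LATS2, 7 higher in HaCaT and 41 lower in HepG2.

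The number of genes changed on average over the lines was set against other splits of the scramble and NF2/LATS2 arrays within lines. Of 100 splits 1 gave as many genes as the real 3754, the real split itself, and the highest of the others gave 3232. A share of 1 in 100 is the lowest that these splits can give. Splits that mix scramble and NF2/LATS2 arrays within a line also widen the spread within groups, which lowers their counts. The rank is therefore limited evidence against chance assignment of these arrays. The spread between replicates was not shown to be biological.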
